A study of Mus musculus with 13 samples.

How the data were processed

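The deposited table held a read count and an FPKM value (fragments per kilobase of gene and per mapped total) for each of 27427 genes in each of 13 libraries, with gene symbols as identifiers, and 18655 of these genes were protein coding. Counts are the unit that the authors' label gives, and the FPKM values are likewise as the authors computed them. Each FPKM value equalled the count divided by the column total and by 1 gene length shared by all libraries, within a relative tolerance of 1e-06. Reads were aligned with HISAT2 per the submitters' processing notes. The aligner version, genome build, annotation, read counter and strandedness are not given in the sources used here. The RNA was total RNA taken with TRIzol, and libraries came from a VAHTS Universal V6 kit, per the labels. The design text states that the submitters lost the raw files. RefSeq gene models on GRCm38.p6 were used only for gene names and for which genes lie beside each other.

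All 13 libraries entered 1 edgeR quasi-likelihood fit with robust dispersion and TMM scaling, with group as the only term and genes kept by the edgeR expression filter, which left 17775 genes. P-values were adjusted by the Benjamini-Hochberg procedure, and a gene was called at an adjusted p under 0.05. Adjusted p-values of genes below are these edgeR values unless another tool is named. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, with version 1.17.8 of data.table. Gene levels are CPM, counts scaled to library size with TMM factors, as mean and standard deviation over libraries. Library totals ran from 34784079 to 40830237 counts, so that 3 counts stand for 0.0734 CPM in non-DM replicate 1, for example.

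Gene lists of cell types, pathways and tissue parts were written from general knowledge before the data were examined, as were the comparisons, the rule for naming genes and most of the alternative settings. There were 44 lists with 635 distinct symbols, of which 624 were matched to the table (among them 18 through another symbol). Lists were tested with limma camera at its preset correlation of 0.01, then with a correlation estimated from the data and with the rotation test fry, each adjusted over the lists. Members called after adjustment over the list alone are given in those words. A list level is the mean log2 CPM of its members in 1 library, and levels were compared between groups by exact permutation of libraries, 2-sided. The smallest p that this can give is 0.0119 for DM against non-DM, 0.0286 for DM+IL37tg against DM and 0.00476 for DM+IL37tg against non-DM.

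Genes were named by a rule. It takes in each direction the 6 called genes with smallest p that changed at least 2-fold, averaged at least 5 CPM and did not overlap between groups. It adds from each list up to 3 called members with smallest p, or the first member where none was called. It also names genes of the inflammasome and MAPK pathways in every comparison, among them Il1b, Nlrp3, Casp1, Pycard, Il18, Gsdmd, Mapk3, Mapk8, Mapk14, Tnf and Il6. Fold changes of single genes are as fitted. List medians were also bounded by setting members with 3 counts or fewer in a group to 3 counts there. These bounds and the standard errors cover counting error and spread between libraries only.

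Alternative settings changed the test, the scaling, the filter, the libraries in the fit, added terms for tissue content, or left out 1 library at a time. The tests were DESeq2, voom with library weights, surrogate variables, and limma on log2 FPKM with an offset of 1 or 0.1. The scalings were relative log expression and none. A strict filter kept genes at 1 CPM in 3 libraries. Covariates for erythrocyte, hair and tissue content, and the 1121 KEGG and Reactome terms of 15 to 300 genes in the deposited table, were chosen after the data were seen. The erythrocyte and hair levels each parted DM from the other groups without overlap. A call lost with either covariate therefore cannot be assigned to that content rather than to group. Group labels were also shuffled over libraries, in at most 100 splits, and counts were simulated 20 times without any group effect or with the DM effect alone.

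The power of the test was measured on counts simulated from the fitted dispersions with equal group means, in which 100 genes were moved 2-fold and 100 others 4-fold. In DM against non-DM, edgeR recovered 48% at 2-fold and 84% at 4-fold with 6 other genes called. In DM+IL37tg against DM it recovered 32% and 73% with 4 others, and in DM+IL37tg against non-DM 46% and 81% with 7 others. DESeq2 recovered 64% and 93%, 45% and 87%, and 62% and 93%, with 54, 35 and 63 other genes called. Of 4 lists moved 2-fold, camera recovered 4 in each comparison and called 0 others. Genes were simulated independently of each other, so this does not show how often camera calls unmoved lists of correlated genes.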

Results

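The series holds 13 RNA-seq libraries of mouse skin wounds at day 10: 6 from wild-type mice given PBS (non-DM), 3 from wild-type mice given streptozotocin (DM) and 4 from IL-37 transgenic mice given streptozotocin (DM+IL37tg). Streptozotocin is a toxin of pancreatic beta cells used to induce diabetes, and IL-37 is an anti-inflammatory cytokine of the IL-1 family. Libraries held 34784079 to 40830237 counts in non-DM, 38759039 to 40547002 in DM and 40075740 to 40795033 in DM+IL37tg. DM libraries had TMM factors of 0.75, 0.917 and 0.889, against 1.006 to 1.135 in the others. The first principal component held 41.1% of the variance, and on it DM replicate 1 lay at 174.3 and the other DM libraries at 71.5 and 69.1. No row for the transgene was found by its symbol, so the transgene itself was not analysed here. The labels do not state that replicates come from separate animals, so p-values measure only the spread between these samples.

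Wounds of diabetic mice had far higher transcript levels of inflammatory mediators, of neutrophil markers, of stress-kinase response genes and of hypoxia genes than wounds of non-diabetic mice at the same day. Epidermal genes of the wound edge and of the cornified layer were also higher. Genes of hair follicles, pigment cells and cell division were lower, and genes of blood vessels were lower on average. Of 44 lists camera called 17 up and 10 down, and 22 of these 27 were also called with fry but 0 with an estimated correlation. In all, 4324 genes were called between DM and non-DM, 2666 up and 1658 down, and 6779 had an unadjusted edgeR p under 0.05. Of the called genes, 61.66% were up with TMM, 25.67% of 6194 without scale factors, and 26.18% of 6504 on log2(FPKM + 1) values. The median log2 fold change of all genes was -0.07 with TMM, -0.38 without scale factors and -0.19 on log2(FPKM + 1). The count was 2099 without DM replicate 1, 2289 with fat, muscle and sebaceous gland content as covariate, 700 with erythrocyte content as covariate, 1973 with replicate number as a block, 6743 with log2(FPKM + 0.1), and 2146 when a 2-fold change was also asked (1438 up, 708 down).

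Under the naming rule, the increases with the smallest p in DM were those of Dusp1, Csrnp1, Hilpda, Junb, Vps37b and Tiparp, genes of several functions. Dusp1, which encodes a phosphatase that switches off MAP kinases, was 5.69-fold higher in DM (895.9 ± 67.1 against 157.4 ± 13 CPM, adjusted p = 1.05e-06). Junb, an AP-1 transcription factor subunit, rose by a log2 fold change of 2.46 (3.86e-06), and Csrnp1, a transcriptional activator, by 3.78 (3.29e-06). Hilpda, a lipid-droplet protein induced by hypoxia, rose by 3.36 (3.41e-06), Tiparp, an ADP-ribosyltransferase induced by the aryl hydrocarbon receptor, by 3.28 (4.89e-06), and Vps37b, a part of the endosomal sorting machinery, by 1.88 (4.89e-06). Among decreases, the smallest p under the same rule were those of Fads1, a desaturase of polyunsaturated fatty acids (-1.19, adjusted p = 0.000115), the centrosome protein gene Cep131 (-1.38, 0.000356) and the Wnt receptor gene Fzd2 (-1.28, 0.000528).

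Inflammatory mediators and the NF-kB response rose together in the diabetic wounds. Of 18 cytokine and chemokine genes, 12 were called up and 0 down, with a median log2 fold change of 4.42 (camera adjusted p = 8.16e-09, adjusted p = 0.342 with an estimated correlation). Without DM replicate 1, a fit that tested 20 genes of the list, the median was 2.67 with 9 up. Among the members Ptgs2, the inducible cyclooxygenase, rose by 5.74 ± 0.77 (381.1 against 7.14 CPM), Cxcl1, which attracts neutrophils, by 4.93 ± 0.68, and Nos2, the inducible nitric oxide synthase, by 3.91 ± 0.43. Tnf was higher by 5.52 ± 0.95 (118.1 ± 90.2 against 2.579 ± 2.31 CPM, adjusted p = 0.00224), while Il6 was not called (1.45, 0.142). Of 14 NF-kB output genes, 13 were up and 0 down, with a median of 1.06 (adjusted p = 6.51e-13, adjusted p = 0.129 with an estimated correlation). These included the feedback inhibitors Tnfaip3 (2.31) and Nfkbia (2.26) and the co-activator Nfkbiz (2.43). In the IL-1 family list 7 of 15 genes were up and 0 down, median 1.36 (adjusted p = 7.3e-06, adjusted p = 0.208 with an estimated correlation), and 8 up and 1 down when adjusted over the list alone. Both the agonist Il1a (4.12 ± 0.52) and the antagonists Il1rn (3.55 ± 0.44) and Il1r2, a decoy receptor (2.77 ± 0.22), were higher. Interferon-stimulated genes stayed apart from this response, with 2 of 18 up and 0 down (median 0.11, adjusted p = 0.491), although the list was called up with erythrocyte content as covariate (0.00195) and 0 were called without DM replicate 1 or non-DM replicate 5.

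Neutrophil transcripts rose with these mediators, macrophage lists were called only in some settings, and lymphoid lists were not called in the main one. Of 15 neutrophil markers, 12 were up and 0 down, with a median log2 fold change of 3.86 (adjusted p = 3.72e-08, adjusted p = 0.342 with an estimated correlation). Retnlg, a secreted protein of neutrophils, rose by 5.23 (49.76 against 1.327 CPM) and Mmp8, the neutrophil collagenase, by 2.99. The mean level of the neutrophil list was 5.15 ± 0.27 log2 CPM in DM and 0.68 ± 1.11 in non-DM (exact permutation p = 0.0119). Of 12 pro-inflammatory monocyte and macrophage markers, 7 were up and 0 down (median 1.69, adjusted p = 0.000826, adjusted p = 0.465 with an estimated correlation), and the list was not called with hair follicle content as covariate (0.329, 2 up and 2 down), and without DM replicate 1 had 4 up. Among its members were the formyl peptide receptors Fpr1 (6.34) and Fpr2 (5.35) and Clec4e, a receptor for mycobacterial glycolipid and dead cells (6 ± 1.25). Pan-macrophage markers had 4 of 12 up and 0 down (median 0.68, adjusted p = 0.00313, adjusted p = 0.57 with an estimated correlation, and 0.64 with hair follicle content as covariate), or 1 up without DM replicate 1, led by Cd14, the lipopolysaccharide co-receptor (5.44, 1192 against 27.4 CPM). Markers of repair macrophages were mixed, with 2 of 13 up and 1 down (median 0.59, or -0.25 without DM replicate 2, adjusted p = 0.799): the arginase gene Arg1 rose by 4.67 and the alternative-activation marker Retnla fell by 3.77, a call lost without non-DM replicate 5 or DM replicate 1 or 2 (largest adjusted p 0.0856). Lists not called were T and NK cells (1 up, 1 down of 14, median -0.13, adjusted p = 0.691, called down with hair follicle content as covariate, 0.0379), gamma-delta T cells (0 up, 1 down of 3, -0.42, 0.491) and B and plasma cells (0 called of 5, 0.35, 0.691). Dendritic and Langerhans cell markers had 0 of 13 called (-0.28, 0.0976, called down without DM replicate 3, 0.0332, with replicate number as block, 0.041, without filter, 0.0393, and with hair follicle content as covariate, 0.0482). Mast cell markers had 1 of 7 up and 1 down (median 0.17, camera direction down, adjusted p = 0.852), but the list was called up without DM replicate 1 (0.035) and with erythrocyte content as covariate (0.0301). Of its called members, Hdc, which makes histamine, rose by 5.86 ± 0.90, and Kit, the stem cell factor receptor gene, fell by 1.46 (0.0256, and 0.0791 without DM replicate 1).

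The NLRP3 inflammasome sensor and its cytokine rose in diabetic wounds at the transcript level, while most other inflammasome parts did not. Of 14 list genes 5 were up and 0 down, median 0.63 and mean 1.44 (adjusted p = 0.00539, adjusted p = 0.457 with an estimated correlation). With hair follicle content as covariate the list was not called (0.307). That covariate was confounded with group (-2.01 to -1.66 log2 CPM in DM, 1.5 to 6.47 in non-DM). Nlrp3 was 63.4-fold higher (181.5 ± 66.6 against 2.868 ± 2.51 CPM, log2 fold change 5.99 ± 0.99, adjusted p = 0.00174) and Il1b 55.0-fold higher (1848 ± 674 against 33.6 ± 40.1 CPM, 5.78 ± 1.28, 0.00768). Aim2, a cytosolic DNA sensor (2.07 ± 0.37, 0.0024), and Mefv, which encodes pyrin (3.17 ± 0.70, 0.0076), rose as well. Il18 was called (0.65 ± 0.20, 0.0333), but not in 9 of the 13 fits that left out 1 library (largest adjusted p 0.21, without DM replicate 1). The adaptor Pycard (0.70, 0.0553, called without non-DM replicate 3, 0.0393, DM replicate 3, 0.0317, or DM+IL37tg replicate 4, 0.0448), the protease Casp1 (-0.06, 0.867) and the pore protein Gsdmd (0.36, 0.403) were not called. Messenger levels do not show whether caspase-1 was active.

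MAPK genes were higher both among the kinases and among the genes that the kinases induce. Of 20 kinase and scaffold genes, 10 were up and 1 down, with a median log2 fold change of 0.42 (adjusted p = 0.000234, adjusted p = 0.342 with an estimated correlation). Map3k8, which links Toll-like receptors to ERK, rose by 1.90 ± 0.22, Map2k3, which activates p38, by 1.04 ± 0.16, and Mapkapk2, a p38 substrate kinase, by 0.82 ± 0.11. Mapk3, which encodes ERK1, was higher by 0.90 ± 0.14 (269.9 ± 55.4 against 144.4 ± 11.1 CPM, adjusted p = 0.0013). Mapk14, which encodes p38 alpha, was higher by 0.43 ± 0.11 (0.0113, and 0.072 without DM replicate 1). Mapk8 (-0.03, 0.874) was not called. The 20 MAPK output genes had a median of 1.65, with 12 up and 1 down (adjusted p = 1.38e-09, adjusted p = 0.099 with an estimated correlation), and 13 up and 4 down when adjusted over the list alone. Ier3, an early survival gene, rose by 4.35 ± 0.42. The kinase list level was 6.15 ± 0.15 log2 CPM in DM and 5.67 ± 0.06 in non-DM, and the output level 6.29 ± 0.21 and 5.01 ± 0.23 (exact permutation p = 0.0119 for each).

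**Figure D1:**
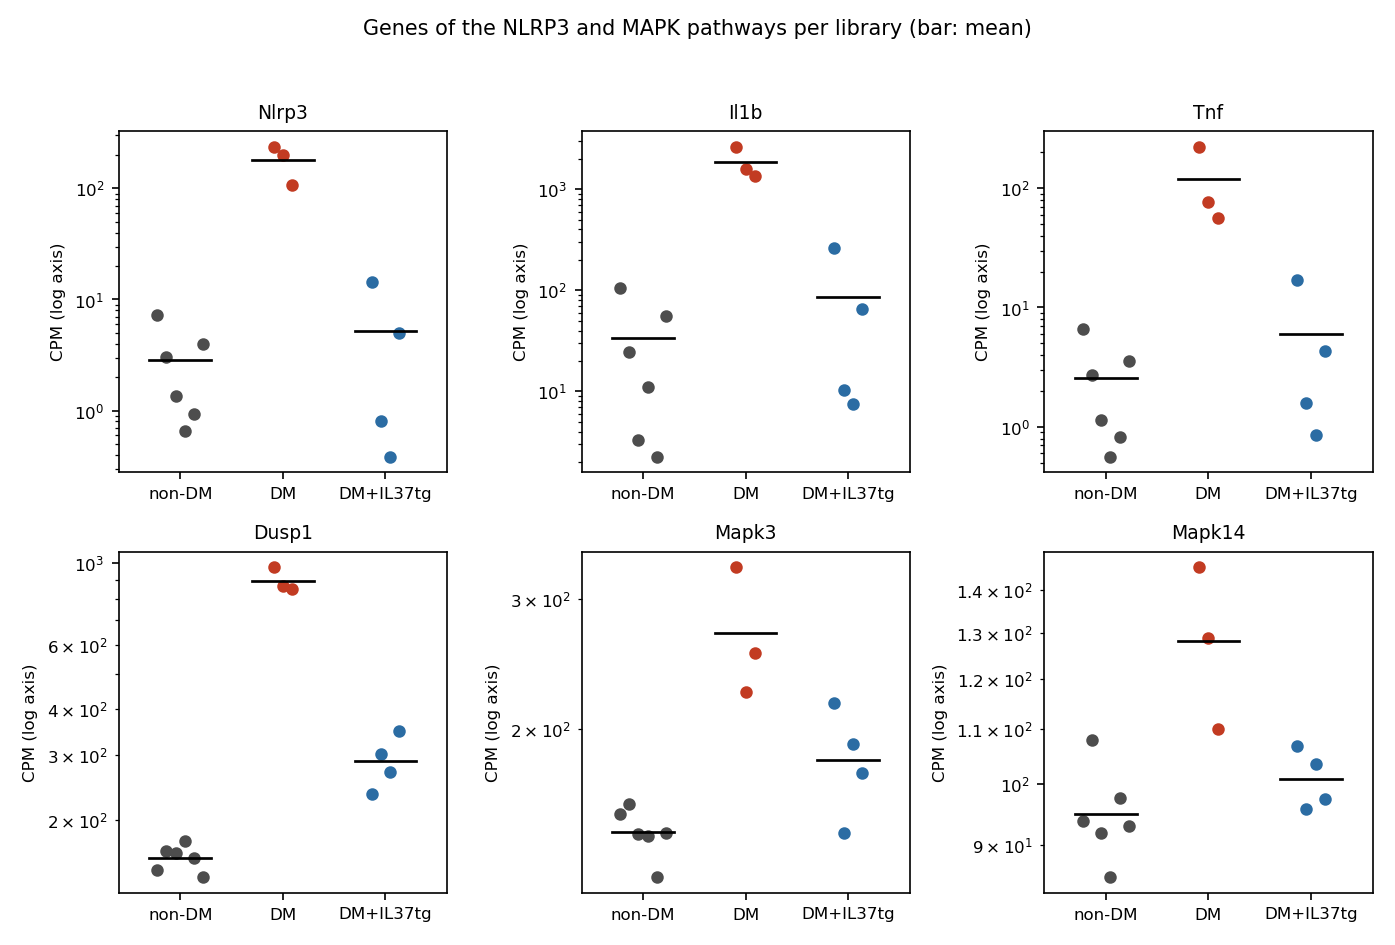
Normalised level (CPM, log axis) of Nlrp3, Il1b, Tnf, Dusp1, Mapk3 and Mapk14 in each library of the 3 groups, with each point a library and each bar a group mean. Nlrp3 averaged 181.5 CPM in DM, 2.868 in non-DM and 5.177 in DM+IL37tg.

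Diabetic wounds carried a strong hypoxia and glycolysis pattern together with several stress programmes. Of 19 glycolysis and hypoxia genes, 18 were up and 0 down, with a median log2 fold change of 1.71 (adjusted p = 3.17e-22, adjusted p = 0.099 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase that HIF induces, rose by 3.17, Pfkfb3, an activator of glycolysis, by 2.41, and Ndrg1, a stress gene of hypoxia, by 2.06. Antioxidant genes had 8 of 13 up and 0 down (median 0.67, adjusted p = 0.00454, adjusted p = 0.457 with an estimated correlation, and 0.164 with erythrocyte content as covariate), or 2 up without DM replicate 1, among them the cystine transporter Slc7a11 (3.96) and the glutathione reductase Gsr (1.46). Glucocorticoid-induced genes had 3 of 11 up and 0 down (median 0.52, adjusted p = 0.00281, adjusted p = 0.168 with an estimated correlation): Per1 rose by 2.26, the mTOR inhibitor Ddit4 by 1.58 and the cell cycle inhibitor Cdkn1a by 1.89. Stress and heat shock genes had 6 of 13 up and 2 down (median 0.45, adjusted p = 0.0115, adjusted p = 0.457 with an estimated correlation, and 0.133 with erythrocyte content as covariate, 0.0502 on log2(FPKM + 1) or 0.0846 with voom weights), with the small heat shock protein gene Hspb1 at 1.29 and Ddit3, which encodes CHOP, at 2.43. Genes of insulin and IGF signalling split, with 4 of 15 up and 1 down (median -0.21, adjusted p = 0.896). The receptor gene Igf1r rose by 0.88 and the adaptor gene Irs2 by 0.70. Fatty acid oxidation genes had 1 of 16 up and 0 down (0.09, 0.917).

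Respiratory chain, clock and ribosome lists moved little, and the calls of respiratory chain and clock genes depended on the setting. Nuclear oxidative phosphorylation genes had 0 of 19 up and 2 down, median log2 fold change -0.19 (adjusted p = 0.0811). That list was called without non-DM replicate 1 (0.047), 2 (0.0332) or 6 (0.043), or without DM replicate 1 (0.023), without filter (0.0393) or scale factors (0.0105), on log2(FPKM + 1) (0.00113) or log2(FPKM + 0.1) (0.00392), with voom weights (0.0103), and with hair (0.00987) or erythrocyte (0.00115) content as covariate. None (0) was down without DM replicate 1. The succinate dehydrogenase subunit gene Sdhb was lower by a log2 fold change of -0.70, and not called without DM replicate 1 or 3 (largest adjusted p 0.0842). The mitochondrially encoded list, whose reads can also come from nuclear copies, had 3 of 13 down and 0 up (-0.37, adjusted p = 0.0369, adjusted p = 0.58 with an estimated correlation). Leaving out any 1 DM replicate left 1 down. Its call was lost without non-DM replicate 3 (0.065), 4 (0.0503) or 5 (0.0559) or DM replicate 2 (0.0766) or 3 (0.152), with the strict filter (0.053), the 2 groups alone (0.0519), the block (0.0915) or a surrogate variable (0.0566). Circadian genes had 3 of 15 up and 0 down (0.37, adjusted p = 0.0308, adjusted p = 0.46 with an estimated correlation), Per1 and Ciart (1.74) among them, and were not called without non-DM replicate 3 (0.055) or DM replicate 2 (0.0646) or 3 (0.13), on log2(FPKM + 1) (0.0618) or log2(FPKM + 0.1) (0.068), or with hair follicle content as covariate (0.445). Cytosolic ribosomal protein genes (0 of 20 called, 0.03, 0.852) and sex-linked genes (0 of 5 called, 0.15, 0.799) were not called.

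Diabetic wounds carried more transcripts of both the migrating epidermal edge and the differentiated layers. Whether the samples held more epidermis was not tested. Of 17 wound-edge keratinocyte genes, 9 were up and 0 down, with a median log2 fold change of 2.56 (adjusted p = 2.38e-07, adjusted p = 0.342 with an estimated correlation). Without DM replicate 3, 5 were up. The laminin chain genes Lama3 and Lamb3, whose products form part of the matrix on which keratinocytes crawl, rose by 2.54 and 2.20. Of 20 differentiation genes, 14 were up and 0 down (median 1.34, adjusted p = 2.73e-07, adjusted p = 0.342 with an estimated correlation), among them the cornified envelope protein gene Lor (2.01, 6075 ± 2515 against 1511 ± 442 CPM), Sbsn (1.26) and the protease gene Klk5 (1.41). Only 6 differentiation genes were up without DM replicate 1. Basal keratinocyte markers had 3 of 8 up and 0 down but a median of 0.13 (adjusted p = 0.266, called up without DM replicate 1, 0.00679, and with hair, 0.0379, or tissue content, 0.0118, as covariate). The basal keratin gene Krt14 rose by 2.26 ± 0.51.

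Hair follicle genes were nearly absent from all 3 DM libraries, and pigment genes were lower. Of 24 hair follicle genes, 10 were down and 0 up, with a median log2 fold change of -8.66, or -7.78 when DM levels of 8 members were set to the counting floor (adjusted p = 2.73e-07, adjusted p = 0.465 with an estimated correlation). Without DM replicate 1, 3 were down and the median was -9.20. Krt85, a keratin of the hair shaft, had 0.00906 CPM in DM (1 count in all) and 105.3 ± 85.5 CPM in non-DM. Krt28 and Krt73, keratins of the inner root sheath, had 0.641 and 0.195 CPM in DM and 138.9 ± 99.2 and 194.7 ± 162.5 CPM in non-DM. The mean list level was -1.80 ± 0.18 log2 CPM in DM and 3.81 ± 2.48 in non-DM (exact permutation p = 0.0238). Non-DM itself was split, with 1.5 to 1.65 in replicates 1, 2 and 5 and 5.55 to 6.47 in replicates 3, 4 and 6. Melanocyte markers had 6 of 8 down and 0 up, median -3.59, unchanged with 1 member at the floor (adjusted p = 0.000579, adjusted p = 0.457 with an estimated correlation, 0.0502 on log2(FPKM + 1) and 0.0617 with hair follicle content as covariate). Without DM replicate 1 the list was called (0.00132) but 0 members were. Their levels were -0.21, 1.08 and 1.56 log2 CPM in the DM libraries, 2.91 to 5.63 in non-DM and 1.6 to 5.83 in DM+IL37tg. Tyr, the tyrosinase gene, had 0.983 CPM in DM and 27.56 in non-DM (adjusted p = 0.0176), and was not called without any 1 of the 3 DM replicates (largest adjusted p 0.08). Sebaceous gland genes were not called as a list (1 of 13 up, 0 down, median -0.28, adjusted p = 0.634).

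Dividing-cell transcripts were lower in the diabetic wounds, vessel transcripts were lower on average, and stromal lists were mixed. Cell cycle genes had 11 of 20 down and 0 up, and 18 down when adjusted over the list alone (median log2 fold change -0.87, adjusted p = 2.73e-07, adjusted p = 0.457 with an estimated correlation). Without DM replicate 3, 3 were down. The replicative helicase genes Mcm6 (-0.68), Mcm3 (-0.66) and Mcm2 (-0.76) were among them. Endothelial and angiogenesis genes had 8 of 18 down and 1 up (median -0.89, adjusted p = 0.00796, adjusted p = 0.62 with an estimated correlation), and the list was not called without DM replicate 2 (0.0686) or with erythrocyte content as covariate (0.471), and leaving out any 1 DM replicate left 3 members down. The angiopoietin receptor gene Tek (-1.26) and the adrenomedullin co-receptor gene Ramp2 (-1.16) fell, whereas the growth factor gene Vegfa rose by 2.85 ± 0.22 (209 ± 76.7 against 29.06 ± 6.31 CPM). Fibrillar collagen and matrix genes had a median of -0.98 with 0 of 19 up and 1 down, the fibrillin gene Fbn1, which was not called without DM replicate 1 or 3 (largest adjusted p 0.127) (list adjusted p = 0.00182, adjusted p = 0.58 with an estimated correlation, and 0.992 in the other direction with erythrocyte content as covariate). Without non-DM replicate 4, 9 matrix genes were down. Endothelial levels in DM were 4.29, 4.16 and 4.07 log2 CPM. They were 3.98 and 4.27 in non-DM replicates 3 and 4 and 4.84 to 5.54 in the other non-DM libraries. Collagen levels in DM were 9.15, 10.17 and 9.88. They were 9.95 and 9.66 in non-DM replicates 3 and 4 and 10.91 to 11.35 in the other non-DM libraries. In both lists DM overlapped with replicates 3 and 4 and was lower only than the other non-DM libraries. Nerve and Schwann cell markers had 4 of 10 down and 0 up, and 0 down with a median of -0.62 without DM replicate 1 (main median -1.11, adjusted p = 0.00454, adjusted p = 0.465 with an estimated correlation, 0.276 with erythrocyte content as covariate and 0.0502 on log2(FPKM + 1)), the Schwann cell gene S100b (-1.76) among them, which was not called without non-DM replicate 5 or DM replicate 1 or 3 (largest adjusted p 0.075). Matrix-degrading enzyme genes had 2 of 17 up and 0 down, with a median of -0.36, a mean of 0.25 and camera direction up (adjusted p = 0.852, called up with erythrocyte content as covariate, 0.00105). Plaur, the urokinase receptor gene, rose by 3.61. Myofibroblast and TGF-beta genes had 3 of 15 up and 2 down, with a median of -0.35, a mean of 0.12 and camera direction down (0.852), or 4 down without non-DM replicate 4. Thbs1, which activates TGF-beta, rose by 3.76 and the contractile gene Tagln fell by 1.04. Lymphatic markers had 0 of 7 called (-0.63, 0.501, called down with hair follicle content as covariate, 0.0321).

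Several tissue lists depended on DM replicate 1, a library nearly without fat, muscle and gland transcripts. Its skeletal muscle level was 1.02 log2 CPM against 5.4 to 10.22 in the other 12 libraries, its adipocyte level -0.43 against 3.61 to 5.69, its sebaceous level 2.86 against 6.29 to 7.61, its mast cell level 1.26 against 4.05 to 5.87 and its nerve level 1.12 against 3.12 to 4.69. Adipocyte markers (median log2 fold change -0.88, 0 up and 1 down of 15, adjusted p = 0.00454, adjusted p = 0.62 with an estimated correlation) were not called without DM replicate 1 (0.0842). The same held for muscle markers (-1.11, 0 called of 17, 0.0115, adjusted p = 0.694 with an estimated correlation), which went to 0.451, and for pericyte and smooth muscle markers (-0.93, 0 up and 3 down of 9, 0.0263, adjusted p = 0.457 with an estimated correlation), which went to 0.0842 and had 1 down without DM replicate 2 or 3. The adipocyte and muscle medians were -0.30 and -0.54 without DM replicate 1, and -1.48 and -1.81 without DM replicate 3. All 3 calls were also lost without scale factors, on FPKM values, with voom weights and with tissue or erythrocyte content as covariate (0.0511 to 0.992). The same library had the highest erythrocyte level, 7.9 log2 CPM, against 5.38 and 4.18 in the other DM libraries, 1.99 to 4.04 in non-DM and 1.73 to 3.45 in DM+IL37tg. Of 7 erythrocyte markers, 6 were up and 0 down in DM (median 4.58, or 2.91 without DM replicate 1, adjusted p = 5.33e-05, adjusted p = 0.342 with an estimated correlation). Alas2, which starts haem synthesis in red cell precursors, had 83.37 ± 96.4 against 2.973 ± 1.75 CPM. Counts of the globin genes Hba-a1 and Hba-a2 cannot be told apart with certainty.

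**Figure D2:**
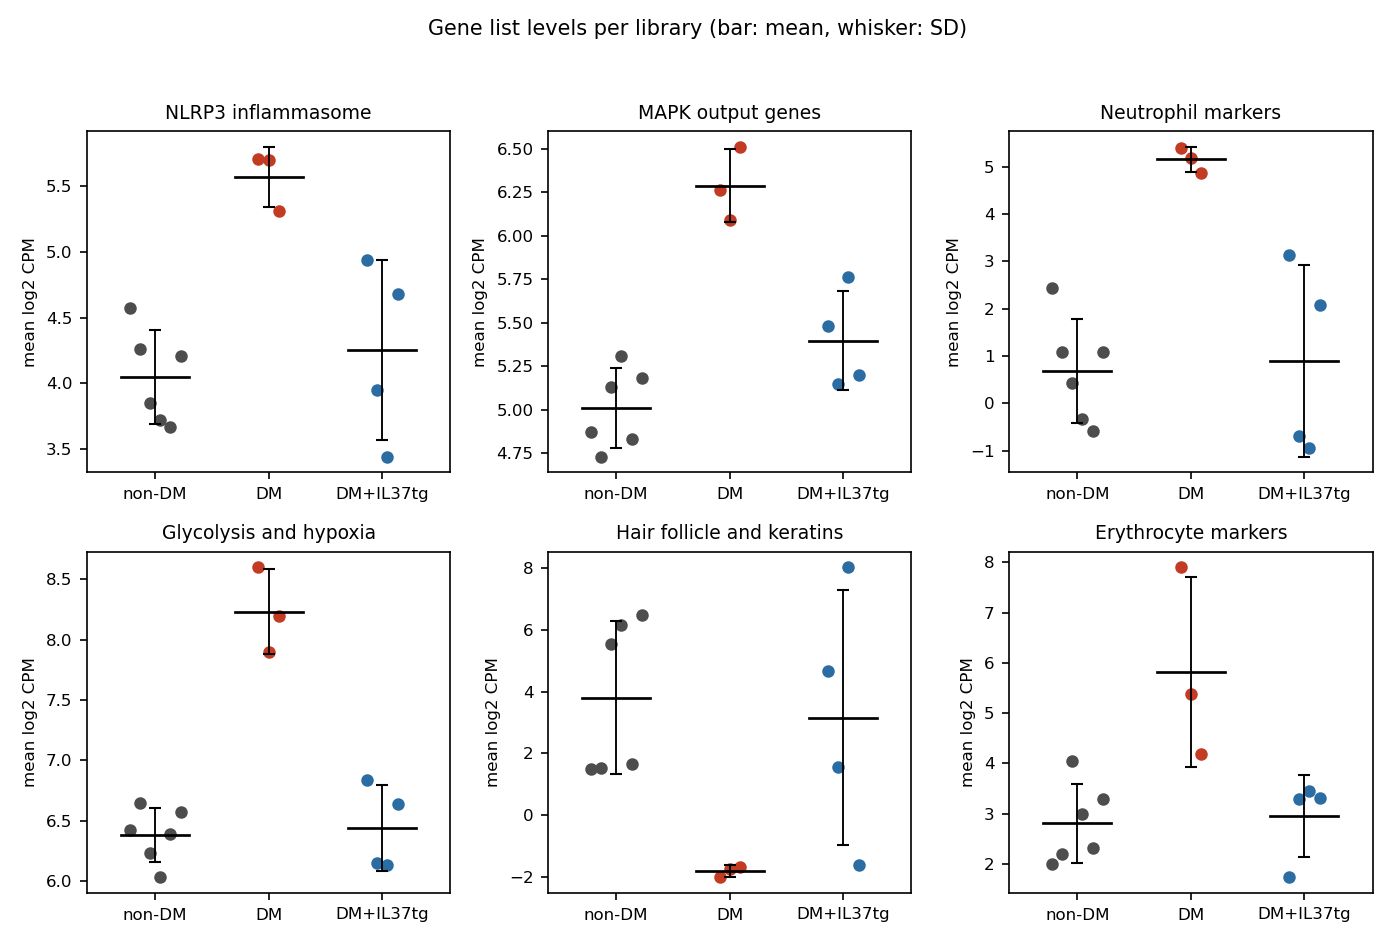
Mean log2 CPM of the members of 6 gene lists in each library of the 3 groups, with bars at group means and whiskers of 1 standard deviation. The neutrophil list averaged 5.15 in DM, 0.68 in non-DM and 0.89 in DM+IL37tg, and the hair follicle list -1.80, 3.81 and 3.16. The DM+IL37tg libraries were uneven in the neutrophil list, at 3.13, -0.7, -0.94 and 2.08.

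In diabetic mice that carried the IL-37 transgene, wounds had lower transcript levels of inflammatory mediators, MAPK response genes and hypoxia genes than wounds of diabetic mice without it. Hair follicle and pigment genes were higher. Most of these changes ran against those of DM. Of 44 lists camera called 6 up and 16 down, and 10 of these 22 were also called with fry but 0 with an estimated correlation. Between DM+IL37tg and DM 1406 genes were called, 359 up and 1047 down, and 4767 had an unadjusted p under 0.05. Of the called genes, 25.53% were up with TMM, against 77.25% of 3363 without scale factors, 72.41% of 3538 on log2(FPKM + 1), 74.95% of 3621 on log2(FPKM + 0.1) and 37.64% of 2694 with DESeq2. The median log2 fold change of all genes was 0.08 with TMM, 0.37 without scale factors and 0.19 on log2(FPKM + 1). The count was 383 without DM replicate 1, 499 without DM+IL37tg replicate 2, 904 without non-DM replicate 6, 294 in a fit of the 2 groups alone, 647 with replicate number as a block, 468 with tissue content as covariate, 67 with erythrocyte content as covariate and 810 when a 2-fold change was also asked (143 up, 667 down).

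Under the naming rule, the decreases with the smallest p in transgenic diabetic wounds were in genes of several functions. Hilpda fell by 3.15 ± 0.23 (20.89 against 185 CPM, adjusted p = 6.1e-05), the non-coding Gt(ROSA)26Sor by 4.67 ± 0.36 (6.33e-05), Sgms2, a sphingomyelin synthase, by 3.01 ± 0.24 (6.99e-05), Csrnp1 by 3.07 ± 0.25 (7.35e-05), the nuclear receptor co-activator gene Pnrc1 by 2.17 ± 0.18 (9.23e-05) and Dusp1 by 1.63 ± 0.14 (288.9 ± 48.9 against 895.9 ± 67.1 CPM, 0.000107). The pheromone receptor gene Vmn2r96, too low in level for the rule and chosen after its values were seen, had a smaller p (adjusted p = 4.5e-05). Its fitted log2 fold change of -10.13 was not bounded, although DM+IL37tg had 1 count in all, against 1000 in DM. Among the increases were Pfn2, an actin-binding profilin (1.71 ± 0.26, 0.00271), Cd320, the receptor for vitamin B12 bound to transcobalamin (1.09 ± 0.16, 0.00276), Cep131 (1.17 ± 0.18, 0.0035) and Alx4, a homeobox factor of skin mesenchyme (4.45 ± 0.79, 0.00693).

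The inflammatory lists were lower with the transgene. Cytokine and chemokine genes had 5 of 18 down and 0 up, and 9 down when adjusted over the list alone, with a median log2 fold change of -3.79 (camera adjusted p = 4.8e-09, adjusted p = 0.342 with an estimated correlation). Leaving out 1 library gave 3 to 8 down, lowest without DM replicate 1 or DM+IL37tg replicate 2 and highest without DM+IL37tg replicate 1, and medians of -4.45 (without DM+IL37tg replicate 1) to -2.57 (without DM replicate 2). Nos2 fell by 4.64 ± 0.52, Ptgs2 by 4.87 ± 0.87 and Cxcl1 by 4.06 ± 0.77. NF-kB output genes had 6 of 14 down and 0 up (median -0.83, adjusted p = 7.05e-10, adjusted p = 0.222 with an estimated correlation), with Tnfaip3 at -1.54, Nfkbia at -1.61 and the adaptor Traf1 at -2.19. IL-1 family genes had 5 of 15 down and 0 up (-1.41, adjusted p = 3.22e-05, adjusted p = 0.305 with an estimated correlation). They included the antagonists Il1rn (-3.05) and Il1r2 (-2.34) and the shared receptor chain Il1rap (-1.41). Neutrophil markers had 5 of 15 down and 0 up, and 12 down when adjusted over the list alone (-3.23, adjusted p = 4.8e-09, adjusted p = 0.342 with an estimated correlation). Without non-DM replicate 6, any 1 DM replicate or DM+IL37tg replicate 2, 3 or 4 only 1 was down, and without DM+IL37tg replicate 1, 8 were. Mmp8 fell by 2.83 ± 0.61. The transgenic libraries were uneven: neutrophil levels ran from -0.94 to 3.13 log2 CPM and cytokine and chemokine levels from -0.11 to 3.52. In both lists DM+IL37tg replicate 1 was highest, above every non-DM library (at most 2.44 and 2.77) and below every DM library (at least 4.87 and 4.94). Pro-inflammatory monocyte and macrophage markers had 3 of 12 down and 0 up (-0.64, adjusted p = 0.000989, adjusted p = 0.559 with an estimated correlation, and 0.304 with hair follicle content as covariate), Fpr1 (-4.58 ± 0.91) among them, or 1 down without DM replicate 1, and pan-macrophage markers 1 of 12 down and 0 up (-0.41, adjusted p = 0.0119, adjusted p = 0.701 with an estimated correlation, 0.177 without DM+IL37tg replicate 3 and 0.917 with hair follicle content as covariate). Interferon-stimulated genes, which were not called as a list in DM, had 2 of 18 down and 0 up (-0.96, adjusted p = 7.41e-05, adjusted p = 0.559 with an estimated correlation, and 0.196 with hair follicle content as covariate), the ubiquitin-like gene Isg15 (-1.76) and the transcription factor gene Irf7 (-1.38). Isg15 was not called without DM replicate 1 or DM+IL37tg replicate 2 or 4 (largest adjusted p 0.12), and Irf7 in 6 of the 13 fits that left out 1 library (0.0812). Without DM replicate 1 or DM+IL37tg replicate 2 or 4, 0 interferon-stimulated genes were down, and without DM+IL37tg replicate 1, 5 were.

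NLRP3 and MAPK genes were lower in the transgenic diabetic wounds, with calls that were less steady for the inflammasome. The NLRP3 list had 3 of 14 down and 0 up, 0 down without DM replicate 1, median log2 fold change -0.39 and mean -1.12 (adjusted p = 0.0223, adjusted p = 0.559 with an estimated correlation, fry adjusted p = 0.0819). It was not called without DM replicate 2 (0.0652), without DM+IL37tg replicate 3 (0.132) or with hair content as covariate (0.395). Nlrp3 was lower by 5.13 ± 1.13 (5.177 ± 6.55 against 181.5 ± 66.6 CPM, adjusted p = 0.0198, and 0.0635 without DM replicate 1 or 0.0541 without DM+IL37tg replicate 2). Il1b was not called (-4.41 ± 1.43, 86.66 ± 121.3 against 1848 ± 674 CPM, 0.0759), although it was without DM+IL37tg replicate 1 (0.0346) and with DESeq2 (0.0079). Tnf fell by 4.31 ± 1.06 (0.0314), and its call was lost without DM replicate 1 (0.128) or DM+IL37tg replicate 2 (0.0865), 3 (0.0522) or 4 (0.0651). Casp1 (0.21, 0.575), Pycard (-0.50, 0.254), Il18 (-0.30, 0.405), Gsdmd (-0.63, 0.235) and Il6 (-1.18, 0.35) were not called.

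MAPK kinase genes had 6 of 20 down and 0 up, and 9 down and 1 up when adjusted over the list alone (median log2 fold change -0.39, adjusted p = 0.000491, adjusted p = 0.342 with an estimated correlation, and 0.0589 with erythrocyte content as covariate). The kinase count was 3 without DM replicate 1. Map3k8 fell by 1.80 ± 0.24 and Mapkapk2 by 0.66 ± 0.13. Mapk3 was called at -0.57 ± 0.16 (0.044), a call kept in only 3 of the 13 fits that left out 1 library (largest adjusted p 0.202). Mapk14 (-0.35, 0.0807) and Mapk8 (-0.03, 0.915) were not called. MAPK output genes had 9 of 20 down and 1 up (median -1.28, adjusted p = 1.05e-06, adjusted p = 0.222 with an estimated correlation), with Junb at -1.94 ± 0.17 and Jun at -1.59 ± 0.21. The kinase list level was 5.76 ± 0.14 log2 CPM in DM+IL37tg and the output level 5.4 ± 0.28 (exact permutation p = 0.0286 for each against DM).

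Hypoxia and epidermal genes were lower as well, and hair follicle and pigment genes higher. Of 19 glycolysis and hypoxia genes, 17 were down and 0 up (median log2 fold change -1.47, adjusted p = 2.02e-26, adjusted p = 0.104 with an estimated correlation), Pfkfb3 by 2.68 ± 0.29, Ndrg1 by 1.97 ± 0.23 and Egln3 by 3.23 ± 0.41. The count was 11 without DM replicate 1. Vegfa fell by 2.61 ± 0.26. Differentiated epidermis genes had 5 of 20 down and 0 up, and 13 down when adjusted over the list alone (-1.10, adjusted p = 1.74e-06, adjusted p = 0.342 with an estimated correlation). Leaving out 1 library gave 0 (without DM replicate 1 or DM+IL37tg replicate 2) to 11 down (without non-DM replicate 5). Wound-edge keratinocyte genes had 2 of 17 down and 0 up (-1.44, or -2.40 without DM+IL37tg replicate 1, adjusted p = 4.18e-05, adjusted p = 0.559 with an estimated correlation). Without DM replicate 2 or 3 or DM+IL37tg replicate 2, 3 or 4, 0 wound-edge genes were down, and without DM+IL37tg replicate 1, 4 were. Hair follicle genes had 7 of 24 up and 0 down, and 23 up when adjusted over the list alone (9.66, or 9.31 at the counting floor, adjusted p = 1.31e-07, adjusted p = 0.559 with an estimated correlation). Without any 1 of the DM replicates 0 hair genes were called, and without DM+IL37tg replicate 3 the median was 6.71. Levels in the transgenic libraries ran from -1.61 to 8.02 log2 CPM. Melanocyte markers had 1 of 8 up and 0 down, and 8 up when adjusted over the list alone (3.15, adjusted p = 0.000632, adjusted p = 0.559 with an estimated correlation). The median was 1.92 without DM+IL37tg replicate 3, and 0 were up in 7 of the 13 fits that left out 1 library, DM replicate 1 among them. The list call was lost on log2(FPKM + 1) (0.156) and log2(FPKM + 0.1) (0.0585) and with hair follicle content as covariate (0.181). Adipocyte markers had a median of 1.31 with 0 of 15 called (adjusted p = 0.000195, adjusted p = 0.559 with an estimated correlation, and 0.818 with erythrocyte content as covariate). Erythrocyte markers had 6 of 7 down and 0 up (-4.03, adjusted p = 1.92e-05, adjusted p = 0.342 with an estimated correlation), or 0 down with a median of -2.56 without DM replicate 1. Cell cycle genes had 0 of 20 called, although the list was called up (0.47, adjusted p = 0.000614, adjusted p = 0.667 with an estimated correlation, 0.0608 without DM replicate 3 and 0.196 with hair follicle content as covariate). Collagen genes (0 of 19 called, 0.16, 0.57) and endothelial genes (0 up and 1 down of 18, 0.04, 0.699), which were called down as lists in DM, were not called with the transgene. Both were called down with erythrocyte content as covariate (0.00666 and 0.0273). Nerve and Schwann cell markers had 0 of 10 called but were called up as a list (1.04, adjusted p = 0.00675, adjusted p = 0.559 with an estimated correlation), a call lost without DM replicate 1 (0.093), without scale factors (0.0552), on log2(FPKM + 1) (0.134) or log2(FPKM + 0.1) (0.0957), with voom weights (0.0602) and with tissue (0.0586) or erythrocyte content (0.517) as covariate. Glucocorticoid-induced genes had 3 of 11 down and 0 up, Per1 (-1.83), Ddit4 (-1.20) and Cdkn1a (-1.47) (list median -0.12, adjusted p = 0.0291, adjusted p = 0.342 with an estimated correlation), a list not called without DM replicate 3 (0.135) or DM+IL37tg replicate 1 (0.0959), with the 2 groups alone (0.0938), on log2(FPKM + 0.1) (0.0522) or with hair follicle content as covariate (0.181). Stress and heat shock genes went both ways (2 of 13 up and 2 down, -0.25, 0.25, called down without DM replicate 2, 0.0172). The T and NK cell list (0.35, 0.353) was called only with hair follicle content as covariate (up, 0.00653).

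Most DM changes ran back in transgenic diabetic wounds. Of the 4324 genes called in DM, 4291 (99.24%) had the opposite sign in DM+IL37tg against DM, and 1310 were called in the opposite direction against 1 in the same, Pglyrp4. Genes up in DM were called back in 37.7% of cases, 1005 genes against 157 given by n1*n2/N for independent calls, and genes down in DM in 18.4%, 305 genes against 33.49. The 2666 up genes had a median log2 fold change of 1.07 in DM, -0.76 in DM+IL37tg against DM and 0.23 in DM+IL37tg against non-DM, and the 1658 down genes -0.90, 0.60 and -0.24. Part of this excess may come from the shared controls, because both comparisons use the same 3 DM libraries and these cannot be split. In simulated counts without any group effect, 88.74% of the 4324 genes with smallest p had opposite signs and 0 were called back. With the DM effect alone 65.45% had opposite signs and 0 were called back. Each gene was drawn independently in these simulations, without the correlation between genes that real libraries share. They may therefore understate what the 3 shared DM libraries give. The covariance of the log2 fold changes was -1.49, against -0.1955 and -0.1705 in these simulations, and Pearson r was -0.90 against -0.6405 and -0.238, with genes not being independent replicates. The count of genes called back was 355 without DM replicate 1, 477 without DM+IL37tg replicate 2, 848 without non-DM replicate 6 and 63 with erythrocyte content as covariate.

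**Figure D3:**
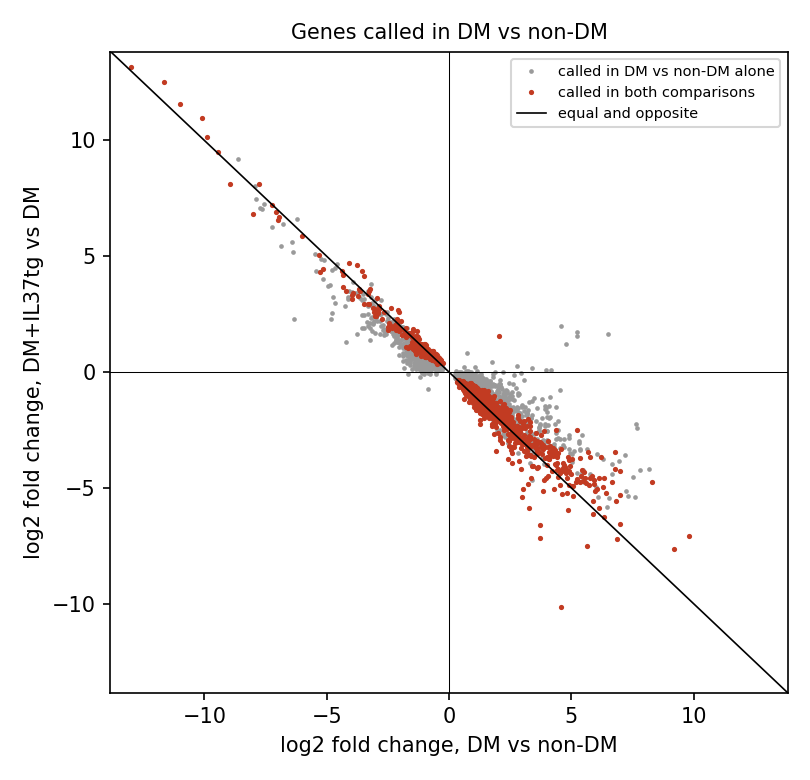
Log2 fold change in DM against non-DM (horizontal) and in DM+IL37tg against DM (vertical) of the 4324 genes called in DM, each point a gene, with red points for genes called in both and a line of equal and opposite change. Red points number 1310 in the opposite direction and 1 in the same.

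Wounds of transgenic diabetic mice were parted from wounds of non-diabetic mice by few genes. Only 10 genes were called between DM+IL37tg and non-DM, 5 up and 5 down, and 1695 had an unadjusted p under 0.05. DESeq2 called 122 genes (64 up, 58 down), and the count was 16 in a fit of the 2 groups alone, 16 on log2(FPKM + 0.1) and 5 with replicate number as a block. With 46% of 2-fold changes recovered by edgeR in simulated counts, many smaller differences would be missed. None of Nlrp3 (0.85 ± 0.86, adjusted p = 0.788), Il1b (1.37 ± 1.09, 0.715), Tnf (1.21, 0.666), Mapk3 (0.33, 0.483) and Mapk14 (0.09, 0.804) was called. The same held for Casp1 (0.16, 0.823), Pycard (0.20, 0.816), Il18 (0.35, 0.579), Gsdmd (-0.27, 0.791), Mapk8 (-0.06, 0.904) and Il6 (0.28, 0.926).

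The called genes mostly parted the transgenic libraries from all others. Pglyrp4, a peptidoglycan-binding antibacterial protein, rose by 3.62 ± 0.35 (32.28 ± 7.89 against 2.618 ± 1.28 CPM, adjusted p = 0.000725), and Tpm3, a tropomyosin, by 1.43 ± 0.17 (0.0039). Muc3, a mucin gene, had 0.654 to 1.054 CPM in DM+IL37tg and 1 count in all 6 non-DM libraries (0.0258), with 28 counts in DM. Acer2, a ceramidase, rose by 1.58 ± 0.22 (0.0158), but was not called without non-DM replicate 2 (0.0993), 3 (0.0808) or 6 (0.0806) or DM+IL37tg replicate 1 (0.0741), 3 (0.0837) or 4 (0.0519). Dusp1 was higher by 0.88 ± 0.12 (0.0132), and not called without non-DM replicate 2 (0.0881), 3 (0.075) or 6 (0.0806) or DM+IL37tg replicate 2 (0.0818) or 3 (0.0613). Among the decreases, the non-coding Gt(ROSA)26Sor had 0.539 to 0.719 CPM in DM+IL37tg and 7.189 to 22.47 in the other 9 libraries (-4.25 ± 0.34 against non-DM, 0.000253). Its reads can include antisense reads of the overlapping Thumpd3, since strandedness is not stated, but Thumpd3 was not called (0.23, 0.533). Wdfy1, an adaptor of endosomal Toll-like receptors, fell by 2.05 ± 0.18 (10.71 against 44.43 CPM, 0.000348), Nmnat1, the nuclear enzyme of NAD synthesis, by 2.72 ± 0.25 (3.313 against 21.88 CPM, 0.000515), and the germ-cell gene Rbm46 by 3.30. The pheromone receptor gene Vmn2r96 had 1 count in DM+IL37tg and 105 in non-DM (0 to 0.022 CPM against 0.201 to 14.42 in the 9 other libraries, 0.0039). Muc3, Vmn2r96, Rbm46 and Thumpd3 lie outside the naming rule and were chosen after their values were seen. Among all tested genes, 74 parted DM+IL37tg from the other libraries without overlap, against 49.72 on average for other choices of 4 libraries, and 8 of the 10 called genes were among them.

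**Figure D4:**
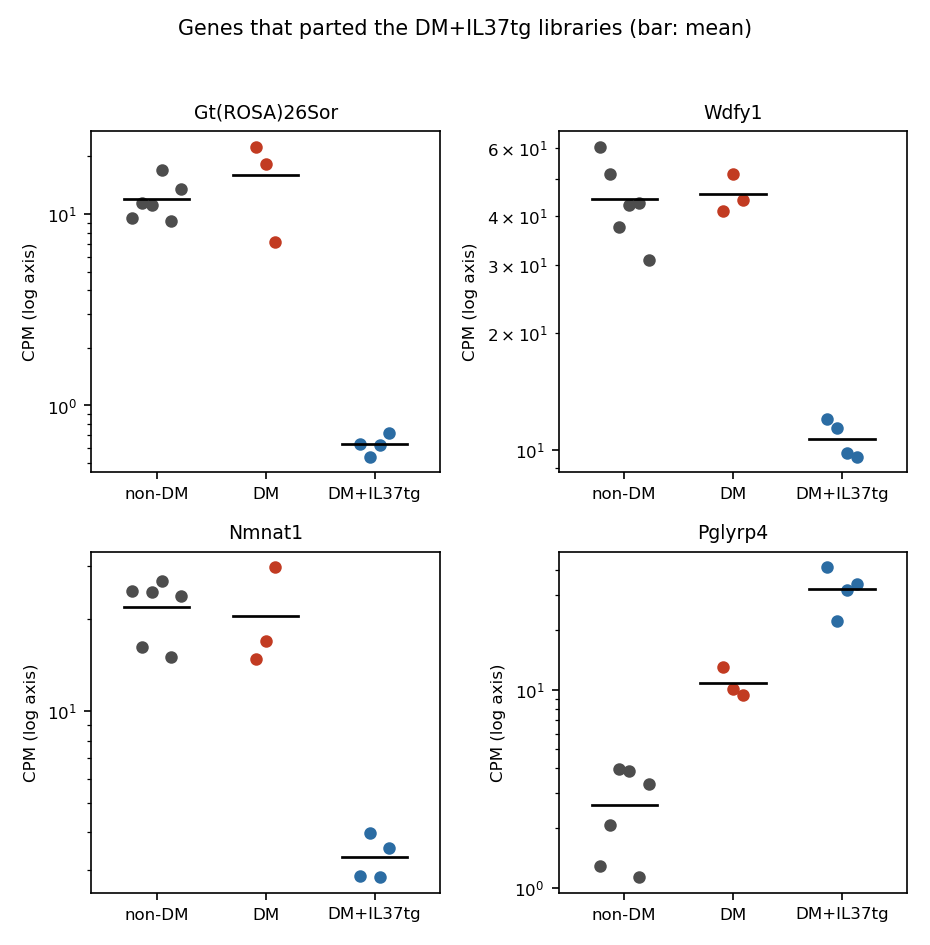
Normalised level (CPM, log axis) of Gt(ROSA)26Sor, Wdfy1, Nmnat1 and Pglyrp4 in each library of the 3 groups, each point a library. Gt(ROSA)26Sor lay at 0.539 to 0.719 CPM in DM+IL37tg and at 7.189 to 22.47 in the others.

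As lists, vessel and matrix genes were lower and MAPK output genes slightly higher in transgenic diabetic wounds than in non-diabetic ones, although only 1 list member was called over all genes. In this comparison 15 lists were called with camera, 9 up and 6 down, 0 with fry and 0 with an estimated correlation, and 7 were called in every fit that left out 1 library. These were endothelial genes (median log2 fold change -0.81, adjusted p = 6.96e-12), collagens (-0.89, 8.07e-09), interferon-stimulated genes (-0.56, 1.11e-07), cell cycle genes (-0.44, 8.23e-07), MAPK output (0.33, 9.36e-05), NF-kB output (0.29, 0.000226) and stress genes (0.14, 0.00605). Each of the 7 had an adjusted p = 0.62 with an estimated correlation. The non-DM libraries were themselves uneven in the first 2 lists. Replicates 3 and 4 had collagen levels of 9.95 and 9.66 log2 CPM and endothelial levels of 3.98 and 4.27, against 10.91 to 11.35 and 4.84 to 5.54 in the other 4, and 9.3 to 10.27 and 3.91 to 4.13 in DM+IL37tg. The exact permutation p of the level was 0.0857 for collagens and 0.0381 for endothelial genes (0.384 adjusted over lists). Dusp1 was the only list member called over all genes, and adjusted over the list alone 15 of 18 endothelial genes were down, 3 MAPK output genes up and 3 NF-kB genes up. Endothelial Tek (-0.83, 0.25), the NF-kB inhibitor Tnfaip3 (0.77, 0.156) and Irf7 (-1.23, 0.25) were not called over all genes. Wound-edge keratinocyte genes were called up (0.84, 0.000565, adjusted p = 0.73 with an estimated correlation), but not without DM+IL37tg replicate 1 (0.318) or with voom weights (0.153). The neutrophil list (1.07, 0.289) was not called, though it was without non-DM replicate 1 (0.0388) or DM+IL37tg replicate 2 (0.0121) or 3 (0.000978). The NLRP3 list (0.19, 0.135) was called up without non-DM replicate 1 (0.0408) or DM+IL37tg replicate 3 (0.00105). MAPK kinases (0.10, 0.155), glycolysis and hypoxia genes (0.12, 0.419) and hair follicle genes (1.15, camera direction down, 0.629) were not called, the last being called up without DM+IL37tg replicate 4 (0.0154) and down without DM+IL37tg replicate 3 (1.27e-05), with a surrogate variable (2.53e-05) and with voom weights (0.01).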

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

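All tests of explanations in this part, the reading of other splits of the libraries among them, were chosen after the results were seen. The check for a library far from the rest of its group was fixed before the data were examined.

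In 5 cases a list level of 1 library lay further from its group than Dixon's test allows at the 95 level, among 176 groups tested, of which chance marks about 1 in 20 groups, or 8.8. Non-DM replicate 5 had a differentiated epidermis level of 7.27 log2 CPM against 8.2 to 8.5 in the other non-DM libraries (gap over range 0.753) and a skeletal muscle level of 10.22 against 8.22 to 8.47 (0.879). Non-DM replicate 1 had an adipocyte level of 3.61 against 4.92 to 5.69 (0.629). DM+IL37tg replicate 1 had a nerve and Schwann cell level of 3.12 against 4.07 to 4.24 (0.853) and an erythrocyte level of 1.73 against 3.3 to 3.45 (0.913). Fewer cases were found than chance gives on average. The 3 DM libraries are too few for this check.

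The first pattern weighed is the rise of inflammatory, hypoxia and MAPK output genes in DM. It does not rest on DM replicate 1 alone, since the median log2 fold change over 86 members of the 5 lists was 1.89 with that library and 1.91 without it, although called members went from 67 to 57. Blood left in the samples was weighed with the erythrocyte level as covariate, which gave a median of 2.04. The quartiles were 1.01 and 4.23, against 1.12 and 3.37 without the covariate, and only 27 members stayed called. The erythrocyte level was confounded with group (4.18 or more in each DM library, at most 4.04 elsewhere). This fit therefore cannot decide whether blood was the cause. A delay between tissue removal and lysis would leave neutrophil markers near their level in non-DM. Their median was 3.86, but this value is the pattern itself and was known when the prediction was written. It therefore cannot test the delay for that part. For the hypoxia genes, with a median of 1.71, and the immediate-early genes, delay and biology cannot be told apart, because handling time is not given and would be confounded with group. An effect of streptozotocin diabetes on the wound may be the source and stays open.

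The second pattern is the near absence of hair follicle transcripts in DM. Less haired skin in the samples would also lower sebaceous gland genes. Without DM replicate 1 the median of the 13 sebaceous genes was 0.18, against -9.2 for hair genes. Their quartiles were -0.11 and 0.46 and their lowest member -0.56. This argues against less haired skin in DM replicates 2 and 3 only as far as the list, which also holds lipid synthesis genes, tracks the glands. DM replicate 1 had a low sebaceous level (2.86 log2 CPM against 6.29 to 7.61 in the other 12 libraries). For that library less haired skin stays open. A stage of the hair cycle unrelated to streptozotocin cannot be told apart from an effect of diabetes: of the libraries outside DM, 1 had a hair follicle level within 0.1 of the highest DM library, DM+IL37tg replicate 4 at -1.61 against -1.66 log2 CPM, above every DM library, and hair-cycle stage is not given for any sample. Hair follicle levels were also split within non-DM, with 1.5 to 1.65 in replicates 1, 2 and 5 and 5.55 to 6.47 in replicates 3, 4 and 6. Either hair-cycle stage or an effect of diabetes may be the source.

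The third pattern is the set of genes that part DM+IL37tg from both other groups. That 1 chromosome segment carried with the transgene holds all of the called genes is excluded, since they lie on 6 chromosomes. Such a segment for part of them stays open. This was tested on 30 placed genes that part DM+IL37tg from the other libraries with an unadjusted p under 0.005. In a window of 300 neighbouring genes 6 of them lay together: Pglyrp4, Tpm3 and Rbm46, which were called against non-DM, and Gm31096, Etv3l and Selenbp2, which were not (adjusted p = 0.134, 0.079 and 0.0667). The permutation p was 0.0069, 0.0023 and 0.0012 for windows of 200, 300 and 500 genes, values that such a segment would give, and 0.26 for 100 genes, so the result turns on the width. An insertion at the Gt(ROSA)26Sor locus could lower that gene (-4.25), but no source used here names an insertion site, so this cannot be told apart from an effect of IL-37 or of strain background.

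Chance as the source of the gene counts was tested by regrouping libraries. For DM against non-DM, 1 of 84 splits, the real one, gave as many genes as the 4324 found, the highest other split giving 1. This is the smallest share that 84 splits can give, and chance is excluded only at that share. For DM+IL37tg against DM, 1 of 35 splits, the real one, reached 1406, which is the smallest share that 35 splits can give. The highest other gave 701, with DM+IL37tg replicate 1 placed with the 3 DM libraries. Chance is excluded only at that share. For DM+IL37tg against non-DM, 3 of 100 drawn of 210 splits, the real one included, reached the real 10. Since other groupings of the same libraries gave as many genes or more, the count of 10 does not exclude chance. The highest other split gave 379, with non-DM replicates 1, 2, 5 and 6 against the rest, which points to a structure of the samples that runs across these groups. In the collagen and endothelial lists non-DM replicates 3 and 4 lie nearer to DM+IL37tg than to the other non-DM libraries (9.95 and 9.66, and 3.98 and 4.27 log2 CPM), so the lower level of these lists in DM+IL37tg against non-DM cannot be told apart from that structure.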

How the results depend on the processing

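Scaling by library totals alone, the covariates and the voom weights were chosen after the data were seen, and the other alternatives were fixed before. Counts called stayed within 1.5 times the main count in every comparison with relative log expression (4311, 1396 and 10), no filter (3672, 1047 and 11), the strict filter, 1 surrogate variable, hair covariate and voom weights. For DM against non-DM the count was otherwise 1973 with replicate number as block, 6504 and 6743 on log2(FPKM + 1) and log2(FPKM + 0.1), 2289 with tissue covariate, 700 with erythrocyte covariate, 2146 with a 2-fold change asked and 2099 to 4662 in leave-one-out. For DM+IL37tg against DM it was 2694 with DESeq2, 294 with 2 groups, 647 with the block, 3538 and 3621 on the FPKM offsets, 3363 without scale factors, 468 with tissue covariate, 67 with erythrocyte covariate, 810 with a 2-fold change and 383 to 1796 in leave-one-out. For DM+IL37tg against non-DM it was 122 with DESeq2, 16 with 2 groups, 5 with the block, 16 on log2(FPKM + 0.1) and 7 to 13 in leave-one-out. Genes called back, 1310 in the main setting, were 2368 with DESeq2, 276 with 2 groups, 605 with the block, 3129 and 3233 on the FPKM offsets, 2998 without scale factors, 435 with tissue covariate, 63 with erythrocyte covariate, 735 with a 2-fold change and 355 to 1633 in leave-one-out. Replicate numbers were not treated as pairs in the main fit, since the labels do not say whether they pair the samples. Over 10 pairs of libraries with the same number r ran from -0.36 to 0.34 and 5 were over 0.1, which does not settle it. The NLRP3 list lost its call with the hair covariate (adjusted p = 0.307 for DM against non-DM and 0.395 for DM+IL37tg against DM), with fry in the latter (0.0819) and in leave-one-out there (0.00703 to 0.132). MAPK kinases in DM+IL37tg against DM lost theirs with erythrocyte covariate (0.0589). With an estimated correlation adjusted p was 0.457, 0.342 and 0.099 for NLRP3, MAPK kinases and MAPK output in DM against non-DM, 0.559, 0.342 and 0.222 in DM+IL37tg against DM, and 0.62 for MAPK output in DM+IL37tg against non-DM. Direction turned in 10 list results: mast cells in DM against non-DM without DM replicate 1 (0.035, leave-one-out range 0.035 to 0.993) and with erythrocyte covariate (0.0301), hair follicle (0.0154 and up, range 1.27e-05, a call down without DM+IL37tg replicate 3, to 0.757) and ribosomal genes (0.974, range 0.000131 to 0.974) in DM+IL37tg against non-DM without DM+IL37tg replicate 4, muscle in DM+IL37tg against DM with tissue covariate (0.0212), and with erythrocyte covariate collagens (0.992 and 0.00666), muscle (0.237 and 0.0221) and adipocytes (0.992). The cause was not tested. Among all settings for named genes, 3020 of 3371 values kept their side of the threshold and direction in DM against non-DM, 2260 of 2699 in DM+IL37tg against DM and 1623 of 1646 in DM+IL37tg against non-DM, and 0 reversed. For lists these were 1118 of 1228, 1115 of 1227 and 1080 of 1227. Values not called in both settings count as kept even where the sign turned. Of 113, 76 and 7 called named genes, 41, 16 and 5 were called in every setting. At depths of 34784079 to 40830237 counts, 32% of simulated 2-fold changes were recovered in DM+IL37tg against DM, which limits what a missing call can show.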

Other observations

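The pathway terms in this part were chosen after the data were seen. Among 1121 KEGG and Reactome terms of the deposited table, camera called 174 up and 90 down in DM against non-DM, 0 of them with an estimated correlation. Among those up in DM were osteoclast differentiation (47 of 116 genes up and 7 down, median log2 fold change 0.43, adjusted p = 2.06e-06), TNF signaling (41 of 112 up and 4 down, 0.29, 4.36e-06), IL-17 signaling (36 of 85 up and 5 down, 0.52, 4.54e-06) and sphingolipid metabolism (23 of 51 up and 1 down, 0.48, 4.36e-06). Production of reactive oxygen and nitrogen species in phagocytes also rose (17 of 34 up and 2 down, 0.83, 1.01e-05, adjusted p = 0.961 with an estimated correlation). Among those down were DNA replication (22 of 35 down and 0 up, -0.55, 5.53e-06), cilium assembly (51 of 173 down and 15 up, -0.36, 0.00124) and the TCA cycle (7 of 30 down and 0 up, -0.37, 0.00266), with adjusted p = 0.961, 0.961 and 0.973 with an estimated correlation.

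In DM+IL37tg against DM 62 terms were up and 173 down, again 0 with an estimated correlation. HIF-1 signaling fell (26 of 97 genes down and 1 up, -0.22, adjusted p = 3.78e-05, adjusted p = 0.944 with an estimated correlation), as did NOD-like receptor signaling (22 of 158 down and 0 up, -0.27, 3.78e-05, 0.973) and sphingolipid metabolism (8 of 51 down and 0 up, -0.38, 8.22e-05, 0.944). Mitochondrial translation (4 of 86 up and 0 down, 0.29, 3.78e-05, 0.979) and DNA replication (3 of 35 up and 0 down, 0.43, 5.34e-05, 0.973) rose. In DM+IL37tg against non-DM 83 terms were up and 57 down, with cholesterol biosynthesis higher (0 of 27 called, 0.34, 4.08e-06) and collagen formation lower (0 of 69 called, -0.56, 5.3e-07), each with adjusted p = 0.986 with an estimated correlation.

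The share of mitochondrially encoded counts was 2.51 ± 0.435% in non-DM, 1.56 ± 0.106% in DM and 2.10 ± 0.268% in DM+IL37tg, and the 10 most abundant genes held 11.2 ± 2.52%, 12.5 ± 2.06% and 8.86 ± 1.12% of counts. Between 20057 and 21477 genes were detected per library. Within groups the correlation between libraries was 0.909 to 0.982, and the chi-square per gene of 44.7 to 384.3 between pairs of libraries shows that none was a copy of another.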
